A study of Mus musculus with 2 samples.

How the data were processed

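H3K4me2 was measured by ChIP-seq in kidney tissue of B6NCrl mouse embryos of both sexes at embryonic day 15.5. Per the labels, there were 2 biological replicates of 1 technical replicate each, pooled from 78 and 62 embryos, with libraries of 300 to 500 bp. Each replicate is a separate pool of embryos of the same strain. Both formed 1 group, so no groups were compared and no test between samples was possible.

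The analysis started from 4 deposited peak lists in mm10 coordinates: the peaks of each replicate, the peaks of both replicates pooled, and the replicated peaks. Per the notes deposited with the files, each replicate's list came from its own alignments and its own control library, the pooled list came from both alignments and 2 control libraries, and the replicated list was derived from the other 3. The peak caller, its threshold, the aligner and the rule that selected the replicated peaks are not given in the sources used here. Each list has the narrowPeak layout of columns, and the columns were read by that layout because no header states their units. The authors' fold enrichment was read as a linear ratio of the ChIP signal over the control at the peak, with values from 1.2 to 82.9 across the lists. The authors' significance of a peak was deposited as −log10 of its p-value, which was above 2 in every list, and as −log10 of its q-value. The authors' display score was deposited as well and was used in no test. The offset of the summit from the start of the peak, as deposited, gave the position of the summit. The lists were made by the authors at a lenient threshold: 7.92% and 8.40% of the peaks of replicates 1 and 2 had a −log10 q under 2. The share was 6.97% of the pooled peaks and 0.329% of the replicated peaks, which are a subset of the pooled peaks. Per-peak values were used only to describe, rank or filter peaks. Each such use stayed within a list except for these shares and the rank correlation of overlapping peaks.

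The lists hold no read counts, so the depth of each library is unknown and no interval from counting could be given. A weak region missed for lack of depth cannot be told from one without the mark. The error given with a value is the SD of the value computed from each replicate's own peaks (n = 2), while the value itself came from the replicated list unless stated otherwise. As the replicated list was called on pooled data, its value can lie outside the range of the replicates.

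Genes and transcription start sites were taken from GENCODE mouse release 21 on GRCm38, the same assembly as mm10. The annotation gave 21742 protein-coding genes with 49776 TSSs on the 19 autosomes and both sex chromosomes, and 23 gene records that shared a symbol with another were left out. No peak lay beyond the end of its chromosome. Peaks on unplaced or unlocalized scaffolds were left out of every comparison. Calculations were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots were drawn with matplotlib 3.10.9.

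Replicates were compared by the share of peaks overlapped by at least 1 bp, against 100 random placements of the other list within its chromosomes with assembly gaps left out, and by Spearman's rho of the fold over overlapping peaks. A summit within 1 kb of a protein-coding TSS counted as a promoter summit, and the remaining summits were assigned to exons, introns or intergenic sequence in that order, against 100 random placements. A gene was marked if a peak lay within 1 kb of any of its TSSs. Breadth was the number of base pairs covered within 5 kb either side of the TSS, a window of 10001 bp, taken at the TSS with the most covered base pairs. Distal peaks were those over 2.5 kb from any protein-coding TSS, assigned to the gene of the nearest TSS within 500 kb. Domains were replicated peaks merged across gaps of up to 1 kb.

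The 19 gene lists were nephron progenitor, ureteric bud and collecting duct, podocyte, proximal tubule, loop and distal tubule, stroma, endothelium, immune, erythroid, adrenal cortex, neural crest and peripheral neuron, brain, liver, muscle and heart, germ cell, skin, housekeeping, olfactory receptors, and Wnt pathway ligands and targets. The lists, the tests, the rule for named genes and the other settings were fixed before the data were examined. All symbols were found. Without the 1133 olfactory receptors, a list had 6 to 17 members. Calb1 and Tcf21 were each in a pair of lists. Marking and membership of the 500 longest domains were tested with two-sided Fisher's exact tests, the latter among genes with a replicated peak at the TSS. Breadth and distal peaks were tested by two-sided permutation against 10000 random lists of the same size, which for distal peaks were matched on the decile of the gene's territory, the bases nearer to its TSS than to any other. The p-values were adjusted by the Benjamini-Hochberg method over the 19 lists, with a threshold of 0.05. Hox paralog groups 1 to 11 were compared with groups 12 and 13 by an exact permutation test of the base pairs covered within 2.5 kb of the TSS.

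Matches to 15 fixed consensus sequences, 4 of them chosen as controls from other tissues, were counted on both strands within 250 bp of distal summits. Each peak was paired with a random window of the same width outside the pooled peaks, matched on GC content in bins of 2%, and 95% intervals came from 200 bootstraps of the peaks. The mean GC content was 51.6% in peaks and 51.5% in windows. The reversed but not complemented consensus served as a control. Reversal removes the CpG of the ETS consensus and adds CpG to those of AP-2, CTCF and OCT, so for these the control differs in CpG content. An exact consensus match is neither evidence of binding nor specific to a single protein.

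Named genes were the protein-coding genes in the 10 longest domains, the 10 genes with the most distal peaks, the 3 broadest members and up to 3 unmarked members of each list in alphabetical order, all Hox13 genes, and the genes nearest to the 5 strongest unshared peaks of each replicate. Genes outside this rule are named only where a count is small or the list of an array of genes is given, and these were chosen after their values were seen.

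The alternatives were each replicate's own peaks in place of the replicated list, a −log10 p of at least 5, an overlap of 50% of either peak, the strongest 25000 peaks of each replicate, promoter windows of 2.5 kb and 500 bp, any overlap in place of the summit, the 5′ end of the gene record as the only TSS, breadth within 10 kb, random lists matched on CpG content within 500 bp of the TSS, a distal distance of 5 kb, the mean in place of the median, gaps of 0 and 3 kb, the 250 or 1000 longest domains, a motif window of 100 bp, windows matched on GC and CpG content, and a Hox window of 1 kb. The omission of Hox genes from every list was added after the results were seen.

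The calculations were tested on simulated data. All 3000 of 3000 planted shared peaks among 5000 per list were recovered. The breadth test called 99 of 100 planted lists of 12 genes and 0 of 280 unchanged lists. Planted genes were all marked and drawn at 2.2 times the breadth of marked genes. As unchanged lists also held unmarked genes, the rise over them was more than 2.2-fold, and smaller rises were not simulated. The marking test called 100 of 100 lists of 12 genes with no member marked and 0 of 280 unchanged lists, but it called 0 of 100 lists of 12 with every member marked. Complete marking of a list of that size was therefore within what the adjusted test could not tell from other genes. A consensus planted in 10% of 4000 simulated peaks was found in 10.1%, and 0 of the 14 other intervals lay off 1. The simulated peaks and windows were random sequence with equal frequencies of the bases. They do not show how often intervals lie off 1 in genomic sequence.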

Results

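H3K4me2, a dimethylated lysine in the tail of histone H3 that is carried by nucleosomes at promoters and enhancers, was mapped by ChIP-seq in whole kidneys of B6NCrl mouse embryos at embryonic day 15.5, when nephron progenitors, the branching ureteric bud and the first differentiating nephrons lie side by side. The data formed 1 group with 2 biological replicates. Replicate 1 was pooled from the kidneys of 78 embryos and replicate 2 from those of 62 embryos, with both sexes in each pool. Peaks were deposited for each replicate, for both replicates pooled, and as a list of replicated peaks. Read counts were not analysed here, so the depth of each library is unknown and no counting interval is given. The labels give no second tissue, stage or treatment, so the comparisons implied by the design were between the replicates, between parts of the genome, and between lists of genes. The fold enrichment quoted for a peak is the authors' own value for that peak. Genes and peaks are not replicates, and every test across them describes these peak lists only.

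The strong H3K4me2 regions of embryonic kidney were found in both pools of embryos, and most of the peaks seen in a single pool were weak and lay outside promoters. Replicate 1 had 53529 peaks and replicate 2 had 52948 peaks (mean 53238.5 ± 411, SD, n = 2), covering 54.9 Mb and 56.0 Mb of the genome. A peak of replicate 2 overlapped 80.4% of the peaks of replicate 1 by at least 1 bp, and a peak of replicate 1 overlapped 80.0% of those of replicate 2. When the other list was placed at random 100 times, these shares lay between 4.31% and 4.96%. With the peaks of each replicate divided into 5 equal classes by the authors' p-value, all peaks of the strongest 2 classes were overlapped, compared with 43.6% of the weakest class of replicate 1 and 41.4% of that of replicate 2. Peaks of a single replicate had a median fold of 3.18 in replicate 1 and 3.11 in replicate 2, against 8.67 and 9.18 for peaks that were overlapped. Only 5.41% and 5.87% of the unshared peaks had their summit within 1 kb of the transcription start site (TSS) of a protein-coding gene.

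The strongest peak found in replicate 1 alone reached a fold of 8.56 (chromosome 4, 141895701 to 141896048, mm10) and lay in an intron, with the TSS of Efhd2 nearest at 20.954 kb. The next 4 lay nearest to Gm527, Sh3glb1, Cdkn3 and Rplp1, with folds of 6.54 to 6.80. In replicate 2 the strongest such peak had a fold of 8.07 (chromosome 3, 67867616 to 67868313, mm10), in intergenic sequence upstream of Iqcj. Its next 4 lay nearest to Sox6, Irx1, Agap1 and Lyrm9, with folds of 6.74 to 7.79. The Sox6 peak, 223 bp upstream of a TSS of this transcription factor gene, was the only promoter peak among these 10, and all 10 were also in the pooled list. Across the 43045 overlapping regions, the fold values of the replicates had a Spearman's rho of 0.828. This correlation is across regions, which are not independent, and it has no p-value.

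**Figure D1:**
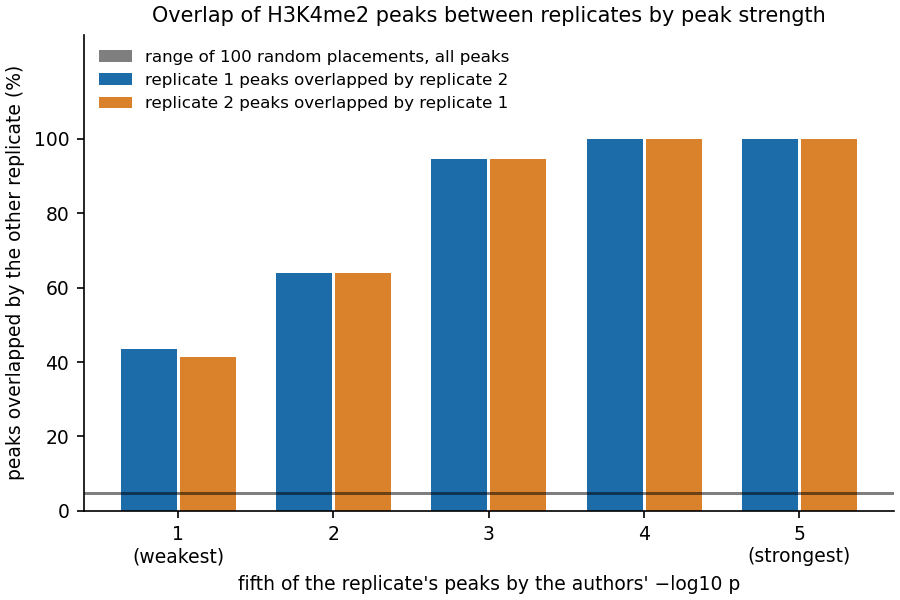
Percentage of each replicate's peaks overlapped by a peak of the other replicate (vertical axis), in 5 equal classes by the authors' p-value from the weakest to the strongest (horizontal axis), with the level given by random placement. The share ran from 43.6% and 41.4% in the weakest class to 100% in the strongest 2.

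The replicated list held 42191 peaks, all of them also present in the pooled list of 59210 peaks, or 71.3% of that list by number and 92.8% of its covered length. The peaks that were kept had a median width of 955 bp and a median fold of 9.28. Those that were not kept had a median width of 240 bp, a median fold of 2.70 and a highest fold of 4.92. All 38472 pooled peaks that overlapped a peak in each replicate by at least 50% of either peak were in the replicated list, together with 3719 others. Of the peaks that were kept, 3636 did not overlap a peak of both replicates by even 1 bp.

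H3K4me2 in the embryonic kidney was concentrated at gene starts, and the promoter peaks were stronger and wider than those elsewhere. Of the 42180 replicated peaks on the assembled chromosomes, 36.3% had their summit within 1 kb of the TSS of a protein-coding gene, 15.3 times the share at random positions. Other exons held 8.50% of summits (1.88 times random), introns held 30.4% (0.719 times) and intergenic sequence held 24.8% (0.488 times). Promoter peaks had a median fold of 32.4 and a median width of 2132 bp, compared with 4.45 and 626 bp for intronic peaks and 5.56 and 651 bp for intergenic peaks. The promoter share was 31.5% in replicate 1 and 31.9% in replicate 2. The strongest replicated peak had a fold of 82.9 (chromosome 11, 49901171 to 49902904, mm10) and lay at the TSS of Rasgef1c, a gene picked for mention here after its value was seen.

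Around the TSS, the strongest point of a peak lay more often on the transcribed side. The 100 bp bin with the most summits was that from 100 to 200 bp downstream of the TSS, with 1980 summits, whereas the 100 bp just upstream of the TSS held 795. Between 300 and 1500 bp from the TSS, 2.90 times as many summits lay downstream as upstream (6880 and 2375). The mean density of summits 300 to 1500 bp downstream was 0.502 of that within 150 bp of the TSS, and it was 0.533 and 0.565 in replicates 1 and 2.

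**Figure D2:**
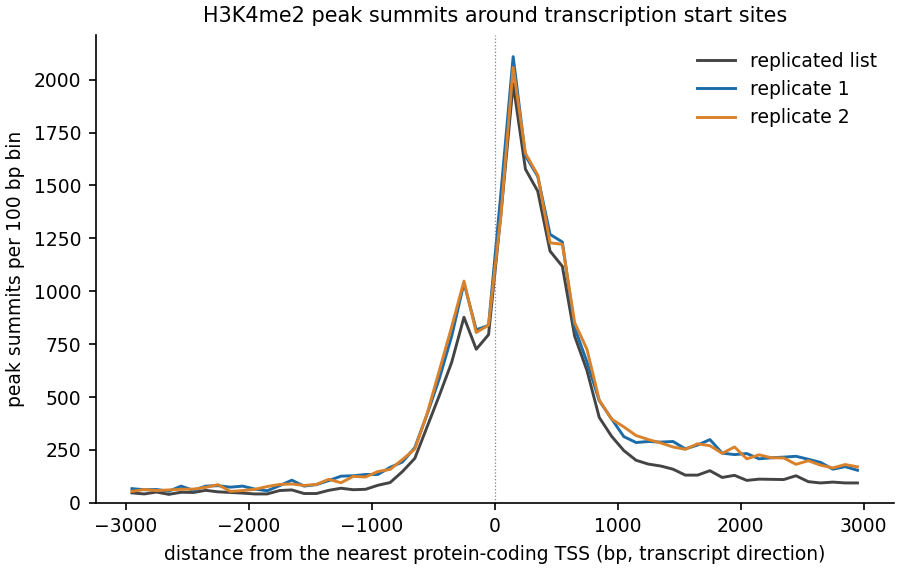
Number of peak summits per 100 bp bin (vertical axis) by distance from the TSS of protein-coding genes in the direction of transcription (horizontal axis), for the replicated list and for each replicate. The highest bin lies 100 to 200 bp downstream of the TSS, with 1980 summits in the replicated list.

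At the level of single genes, 14951 of 21742 protein-coding genes (68.8%) had a replicated peak within 1 kb of a TSS. Replicate 1 alone marked 15014 genes and replicate 2 alone marked 15007, and 14884 genes were marked in both.

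All 15 genes of the nephron progenitor list, including Six2, Pax2 and Wt1, transcription factor genes needed for nephron formation, carried the mark at the promoter, compared with 68.7% of other genes. In the ureteric bud and collecting duct list 16 of 17 genes were marked, and the exception was Aqp2, the water channel of the mature collecting duct. The podocyte (12 of 12), endothelium (10 of 10), Wnt (12 of 12) and stroma (11 of 12) lists were also nearly complete, and the unmarked stromal gene was Ren1, which encodes renin. The Wnt list, fixed as Wnt pathway ligands and targets, also holds the Notch pathway genes Notch2, Jag1 and Lfng and the signals Bmp7 and Fgf8, so its results are not those of the Wnt pathway alone. In the proximal tubule list 8 of 12 genes were marked, of which Cubn and Slc22a6 had no peak there in replicate 2. The unmarked genes included Aldob, Slc3a1 and Slc5a12, which encode a fructose-metabolising enzyme and transporters of the mature tubule. Aldob had a peak within 1 kb of a TSS in replicate 1 but not in replicate 2. In the loop and distal tubule list 5 of 10 were marked, without Cldn16, Kcnj1 and Slc12a1, a claudin, a potassium channel and the sodium-potassium-chloride cotransporter of the loop of Henle.

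Lists for other cell types ranged widely. The immune list had 1 marked gene of 9 (the Fc receptor gene Fcgr3), the liver list 2 of 9 (Apoa1 and Afp), the germ cell list 1 of 7 (Dazl) and the olfactory receptor list 6 of 1133. Marked genes made up 3 of 8 in the erythroid list, 2 of 6 in the adrenal cortex list, 3 of 9 in the muscle and heart list, 2 of 7 in the skin list and 6 of 9 in the neural crest and peripheral neuron list. The brain list had 9 marked genes of 11, among them Emx1, Eomes and Neurog2, transcription factor genes of the developing cortex, while Gfap and Neurod6 were unmarked. All 13 housekeeping genes were marked.

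Of the 19 lists, 6 differed from all other protein-coding genes in two-sided Fisher's exact tests with Benjamini-Hochberg adjustment. The nephron progenitor (100% against 68.7% of other genes, Fisher's exact test, adjusted p = 0.0210) and housekeeping lists (100%, adjusted p = 0.0415) were marked more often. The immune (11.1%, Fisher's exact test, adjusted p = 0.00558), liver (22.2%, adjusted p = 0.0210), germ cell (14.3%, adjusted p = 0.0210) and olfactory receptor lists (0.530%, p too small to be stored) were marked less often. The ureteric bud and endothelium lists (both adjusted p = 0.0587, Fisher's exact test) and the podocyte and Wnt lists (both adjusted p = 0.0558) did not pass. Every member of the endothelium, podocyte and Wnt lists was marked, so no higher marking could have made these lists pass with the 1 kb window. Under Fisher's exact test the adjusted p was 0.0587 for muscle and heart and for skin, 0.118 for adrenal cortex, and 0.152 for stroma and for erythroid. It was 0.360 for loop and distal tubule, 0.581 for brain, and 1 for proximal tubule and for neural crest and peripheral neuron in the same exact tests. With a TSS window of 2.5 kb the nephron progenitor, housekeeping, liver and germ cell calls ended and 2 lists passed, and with replicate 1 alone the housekeeping and liver calls ended. With a window of 500 bp 10 lists passed, with Wnt, podocyte, skin and ureteric bud gained, and with the gene record's own 5′ end as the only TSS 8 passed, with Wnt, adrenal cortex and skin gained and housekeeping lost.

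Of the 19 lists, 7 were covered by the mark over a greater length around the TSS than random lists, namely nephron progenitor, Wnt, ureteric bud, stroma, housekeeping, endothelium and podocyte. Peaks covered the whole 10001 bp window within 5 kb of the TSS at Six2 (9568.5 ± 152 bp, SD, n = 2 replicates) and Pax2 (9862.5 ± 14.8 bp), and 9943 bp of it at Wt1 (9836 ± 93.3 bp). In the ureteric bud list, the covered length was 10001 bp at Hoxb7 (in both replicates as well), 9700 bp at Lhx1 (9566.5 ± 351 bp) and 9618 bp at Gata3 (9627 ± 87.7 bp), transcription factor genes of the nephric duct lineage. Stromal genes reached 10001 bp at Hoxd10, 9579 bp at Pdgfra, which encodes a growth factor receptor of mesenchymal cells, and 9286 bp at Meis1, a homeobox gene of the renal stroma (8885 ± 201 bp). The median over all protein-coding genes was 2142 bp.

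The median breadth was 7588 bp over the nephron progenitor list, 5944.5 bp over the Wnt list, 5811 bp over the ureteric bud list and 5530 bp over the stroma list. The medians of 10000 random lists of the same size were 2120 to 2153 bp, with 95% of them between 0 and 3140 bp for the size of the nephron progenitor list. For each of these 4 lists, and for the olfactory receptor list (median 0 bp), the two-sided permutation p was 0.0002, the smallest that these permutations can give (adjusted p = 7.6e-04). Housekeeping genes also stood above random lists (4567 bp, permutation test, adjusted p = 0.00127), led by Actb at 7115 bp (6067 ± 482 bp), Rpl13a at 6192 bp and Ubc at 5716 bp. The podocyte list had a median of 3848 bp (permutation test, adjusted p = 0.0119), with the transcription factor genes Tcf21 at 8177 bp (8030.5 ± 3.54 bp), Foxc2 at 7692 bp and Mafb at 6780 bp. The endothelium list had a median of 3997.5 bp (permutation test, adjusted p = 0.0161), with Sox17 at 4437 bp and the growth factor receptor genes Flt1 at 4314 bp and Kdr at 4101 bp.

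The other 11 lists did not pass the permutation test, with adjusted p from 0.219 to 0.611. For each, the range of medians of random lists not matched on CpG content began at 0 bp. None of these lists could therefore have passed as narrower in that test. Their medians were 2427 bp for brain, 1373 bp for neural crest and peripheral neuron, 1060.5 bp for proximal tubule, 740.5 bp for loop and distal tubule, 688 bp for muscle and heart, 500 bp for adrenal cortex and 176.5 bp for erythroid, and 0 bp for immune, liver, germ cell and skin. Single members were broad all the same, such as Pou3f3, a transcription factor gene of the distal nephron, at 8738 bp (8283.5 ± 357 bp, SD, n = 2), Irx2 at 6779 bp, and the proximal tubule genes Lrp2, which encodes the endocytic receptor megalin, at 5341 bp (5071 ± 146 bp) and Hnf1a at 4791 bp. Among the other tissues' genes, the broadest were Emx1 at 5547 bp, the macrophage gene Cd68 at 4394 bp, the erythropoietin receptor gene Epor at 3755 bp and the neuronal gene Elavl4 at 3527 bp. Cd68 had no replicated peak within 1 kb of its TSS, so the covered length near a gene can come from peaks beside it. The endothelium call ended with either replicate alone, with a 10 kb window and with the gene record's 5′ end as the only TSS; the podocyte call ended with a 10 kb window; and against random lists matched on CpG content the olfactory receptor call ended while the germ cell list passed as narrower (permutation test, adjusted p = 0.0252).

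**Figure D3:**
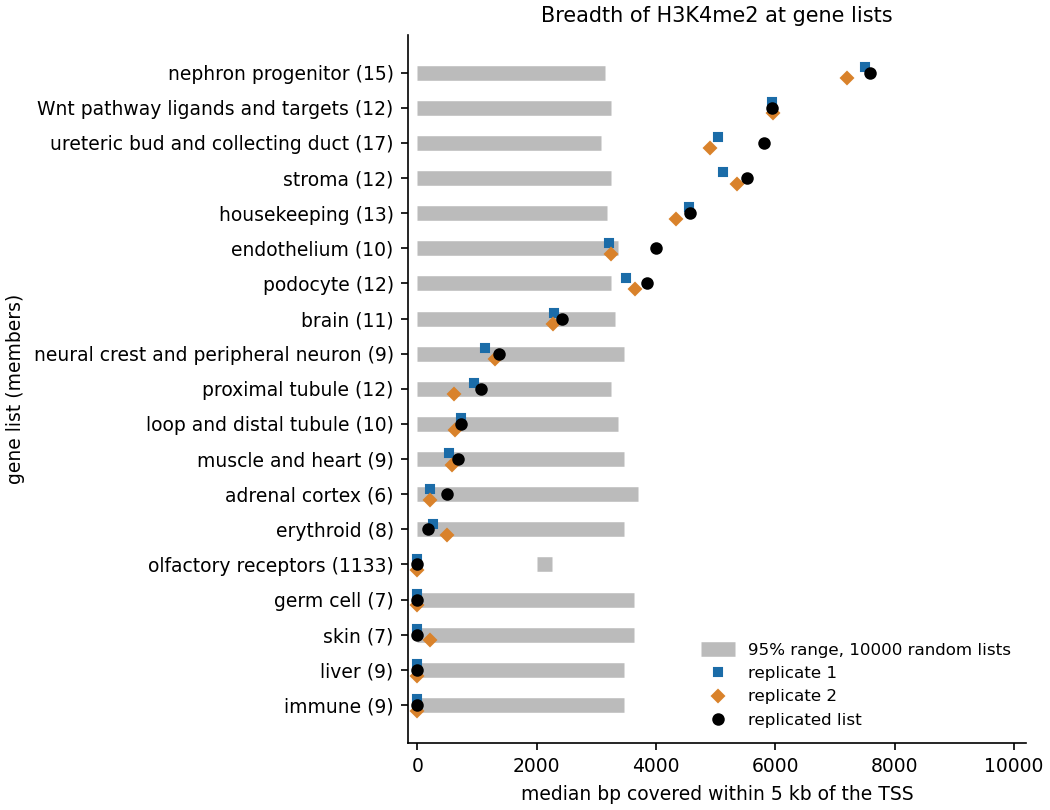
Median number of base pairs covered by peaks within 5 kb of the TSS (horizontal axis) for each gene list (vertical axis, members in brackets), from the replicated list and from each replicate. Grey bars span 95% of the medians of 10000 random lists of the same size. The nephron progenitor median of 7588 bp is the highest.

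Of the 10 longest domains of H3K4me2, 6 lay over the Hox clusters. Peaks merged across gaps of up to 1 kb gave 35727 domains with a median length of 1175 bp, and 107 of them were at least 10 kb long. The longest spanned 86469 bp from Hoxb2 to Hoxb9 (chromosome 11, 96268988 to 96355456, mm10), of which peaks of the replicates covered 82712 ± 253 bp (SD, n = 2). Next came 50497 bp on chromosome 6 with the TSSs of Hoxa3, Hoxa5, Hoxa6, Hoxa7, Hoxa9, Hoxa10, Hoxa11 and the predicted gene Gm28308, 44354 bp on chromosome 2 with those of Hoxd3 and Hoxd8 to Hoxd12, and 29562 bp with Hoxa1, Hoxa2, Hoxa3 and 5730596B20Rik. Outside the clusters, the longest domains lay at Nr2f2 (27607 bp; covered 26283.5 ± 310 bp, SD, n = 2), Gata3 with 4930412O13Rik and 9230102O04Rik (24934 bp), Meis2 (24474 bp) and Tbx3 (24173 bp), all of them transcription factor loci. The 10 longest also held Hoxc4, Hoxc5 and Hoxc6 (26958 bp) and Hoxc9 and Hoxc10 (26074 bp).

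The 500 longest domains held the TSSs of 593 protein-coding genes. Of the nephron progenitor list, 10 of 15 genes lay in them, or 66.7% compared with 3.90% of other marked genes (two-sided Fisher's exact test, adjusted p = 4.3e-10). The shares were 7 of 12 for the Wnt list (Fisher's exact test, adjusted p = 9.4e-07), 7 of 16 for ureteric bud and 6 of 11 for stroma (both adjusted p = 7.0e-06), and 3 of 12 for podocyte (adjusted p = 0.0397). Housekeeping genes had 2 of 13 and the loop and distal tubule list 1 of 5, namely Pou3f3 (Fisher's exact test, adjusted p = 0.291 and 0.497). No marked gene of the other 12 lists lay in these domains, endothelium (0 of 10), brain (0 of 9) and proximal tubule (0 of 8) among them, with adjusted p = 1 in the exact tests of these lists, which had 1 to 10 marked genes each. With gaps of up to 3 kb merged the Wnt and podocyte calls ended, and with the 250 longest domains the podocyte call ended.

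Within the Hox clusters, the homeobox gene arrays that pattern the body axis, the mean covered length around the TSS was greater for paralog groups 1 to 11 than for groups 12 and 13, with exceptions among both. Replicated peaks covered 83.2% of HoxA (79.4 ± 1.08%, SD, n = 2 replicates), 58.6% of HoxB (56.4 ± 0.294%), 61.6% of HoxC (58.5 ± 0.830%) and 76.4% of HoxD (73.7 ± 0.310%), compared with 2.17% of the genome. The HoxB span includes the long stretch from the end of Hoxb13 (96197447) to the start of Hoxb9 (96271457), which holds no other Hox gene. Its share is therefore not a measure of the HoxB genes alone. Hoxa10 and Hoxa11 were covered over all 5001 bp within 2.5 kb of the TSS, as were Hoxd9, Hoxd10 and Hoxd11. Covered lengths were much shorter at Hoxa13 (1768 bp; 1719.5 ± 79.9 bp, n = 2), Hoxb13 (1161 bp; 837 ± 31.1 bp), Hoxc13 (2140 bp; 1853 ± 76.4 bp) and Hoxd13 (1365 bp; 1424 ± 358 bp). Hoxd12, between Hoxd11 and Hoxd13, had 4255 bp (3876.5 ± 124 bp), and Hoxc12 had 1244 bp. Hoxb1 and Hoxd1, at the opposite end of their clusters, had 1713 bp and 2275 bp.

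The 33 genes of groups 1 to 11 had a mean covered length of 4603 ± 808 bp and the 6 genes of groups 12 and 13 one of 1989 ± 1169 bp (SD over genes). The difference of 2614 bp had a two-sided exact permutation p of 1.5e-05. Neighbouring Hox genes share peaks and are not independent. With a window of 1 kb in place of 2.5 kb the difference was 550 bp (exact permutation p = 2.6e-04).

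**Figure D4:**
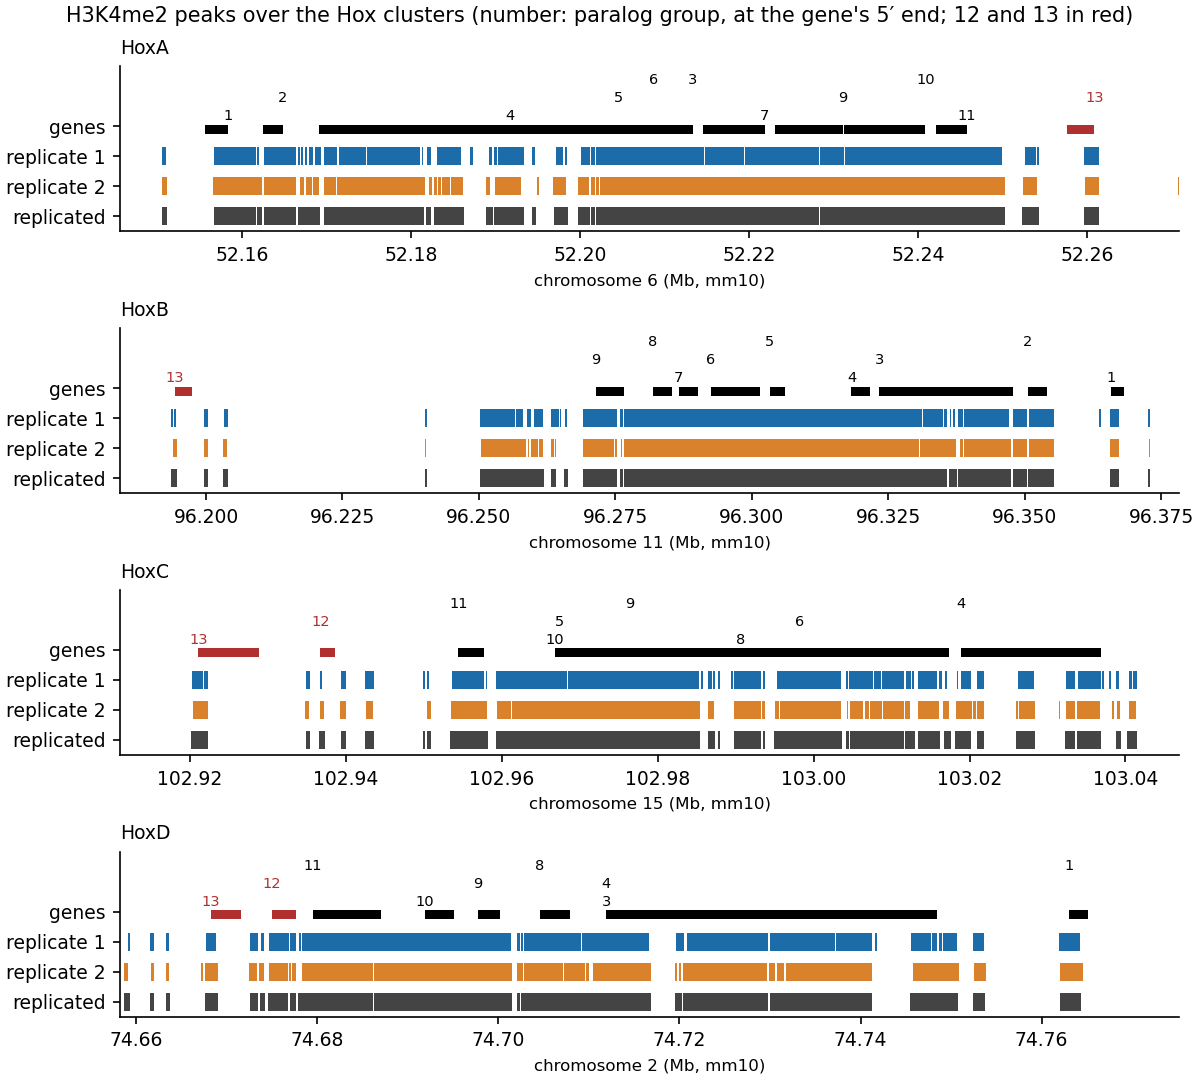
Peaks of replicate 1, replicate 2 and the replicated list over the 4 Hox clusters, drawn to scale along mm10 coordinates in Mb (horizontal axis), with the gene records above and paralog groups 12 and 13 in red. Peaks run almost without a break from Hoxb2 to Hoxb9 and stay short at Hoxa13, Hoxb13, Hoxc13 and Hoxd13.

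Of the replicated peaks, 23886 (56.6%) lay over 2.5 kb from any protein-coding TSS, and 8489 genes had at least 1 such distal peak assigned to them as the nearest gene within 500 kb. The largest number, 48, belonged to Zfhx3, a zinc-finger homeobox gene (61 in each replicate). Gse1 had 35 (55.5 ± 2.12, SD, n = 2), Zfp217 33, Sox9 and Zfp608 30 each, Adgrl2 and Mtx2 29 each, Maml3 and Pbx1 27 each, and Bcor 26; none of these counts is adjusted for the size of the gene's territory. Sox9 encodes a transcription factor of the ureteric tip (31.5 ± 0.707 in the replicates) and Pbx1 a homeodomain protein needed for kidney development (32.5 ± 0.707). Mtx2 encodes a mitochondrial outer membrane protein, and its gene lies beside the HoxD cluster.

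The genes of the Wnt list had a median of 6 distal peaks, among them the Wnt pathway genes Axin2 with 11 (11.5 ± 0.707, SD, n = 2), Lef1 with 9 (11 ± 1.41) and Wnt7b with 7 (9.5 ± 0.707). Among its highest counts were also Notch2, a Notch receptor gene, with 11 and Bmp7 with 10, both chosen for mention after their values were seen. Random lists matched on the size of each gene's territory had a median of 1 (two-sided permutation p = 0.0002, the smallest these permutations can give; adjusted p = 0.0038). None of the other 18 lists passed. None could have passed with fewer peaks, because the range of random medians began at 0 for each. Medians were 3 for nephron progenitor (permutation test, adjusted p = 0.123), ureteric bud (0.0589) and stroma (0.123), and 2.5 for podocyte (0.143) and endothelium (0.298). They were 2 for brain, 1.5 for proximal tubule, 1 for neural crest and peripheral neuron, muscle and heart, and housekeeping, 0.5 for loop and distal tubule and for adrenal cortex, and 0 for immune, erythroid, liver, germ cell, skin and olfactory receptors, with adjusted p from 0.174 to 1 in the permutation tests. The number of lists that passed was 6 with either replicate's own peaks and 5 with the mean in place of the median. It was 2 with replicated peaks of −log10 p of at least 5. Nephron progenitor and ureteric bud were among those gained with either replicate and with the mean. Stroma and podocyte were gained with either replicate but not with the mean.

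Within 250 bp of distal summits, the highest folds over GC-matched random windows among 15 binding consensus sequences were those of CTCF, the protein that anchors chromatin loops, and of HNF1, the homeodomain factors of kidney epithelium. By share of peaks, AP-2 was highest at 19.1% and HNF1 lowest at 0.301%. The CTCF consensus occurred within 250 bp of the summit in 3.59% of 23881 distal peaks, compared with 0.373% of GC-matched random windows, a fold of 9.63 (95% bootstrap interval 7.82 to 12.1). HNF1 matched 0.301% of peaks and 0.0335% of windows (9.0-fold, 5.07 to 23.7), ETS 3.39-fold more peaks than windows (2.26 to 5.45), the long Six2-family consensus 1.79-fold (1.49 to 2.24) and TEAD 1.44-fold (1.29 to 1.68). The reversed consensus was a control with the same bases in the opposite order, though not always the same CpG content. It gave 0.800 for HNF1, 0.784 for ETS, 0.820 for the long Six2-family consensus, 0.804 for TEAD and 1.67 (0.398 to 7.03) for CTCF. Posterior HOX was at 1.39-fold with 1.2 for its reversed consensus, AP-2 at 1.19-fold with 1.73, GATA at 1.10-fold with 0.857 and AP-1 at 1.09-fold with 0.940. HNF4 was not distinguishable from windows (1.07-fold, 0.883 to 1.33; reversed 1.13). The short Six2-family consensus was less frequent in peaks (0.759-fold, 0.725 to 0.795), and its reversed form still less (0.674, 0.644 to 0.710), so the lower frequency was not specific to the motif.

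The intervals of 12 of the 15 consensus sequences lay above 1. These included 3 of the 4 chosen as controls from other tissues, MEF2 (2.41-fold, 1.90 to 2.95; reversed 1.53), OCT (1.57-fold; reversed 1.21) and RUNX (1.22-fold; reversed 0.822), while NEUROD was at 0.921-fold (0.876 to 0.966; reversed 0.715). Folds up to that of MEF2 therefore occurred for consensus sequences chosen as controls from other tissues. Whether factors that recognise these sequences are absent from the kidney was not examined. Within 100 bp of the summit, the CTCF consensus was no more frequent in peaks than in windows (0.872-fold, 0.545 to 1.34), NEUROD was at 1.01-fold, the AP-1 interval included 1, and HNF1 had no match in the windows and hence no fold. Against windows matched on GC and CpG content, AP-2 was at 0.988-fold with 1.24 for its reversed consensus, and the NEUROD interval included 1. ETS was at 1.91-fold with 0.793 for its reversed consensus. HNF4 was at 1.43-fold (1.16 to 1.88), but its reversed consensus also lay above 1 (1.31, 1.02 to 1.81).

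**Figure D5:**
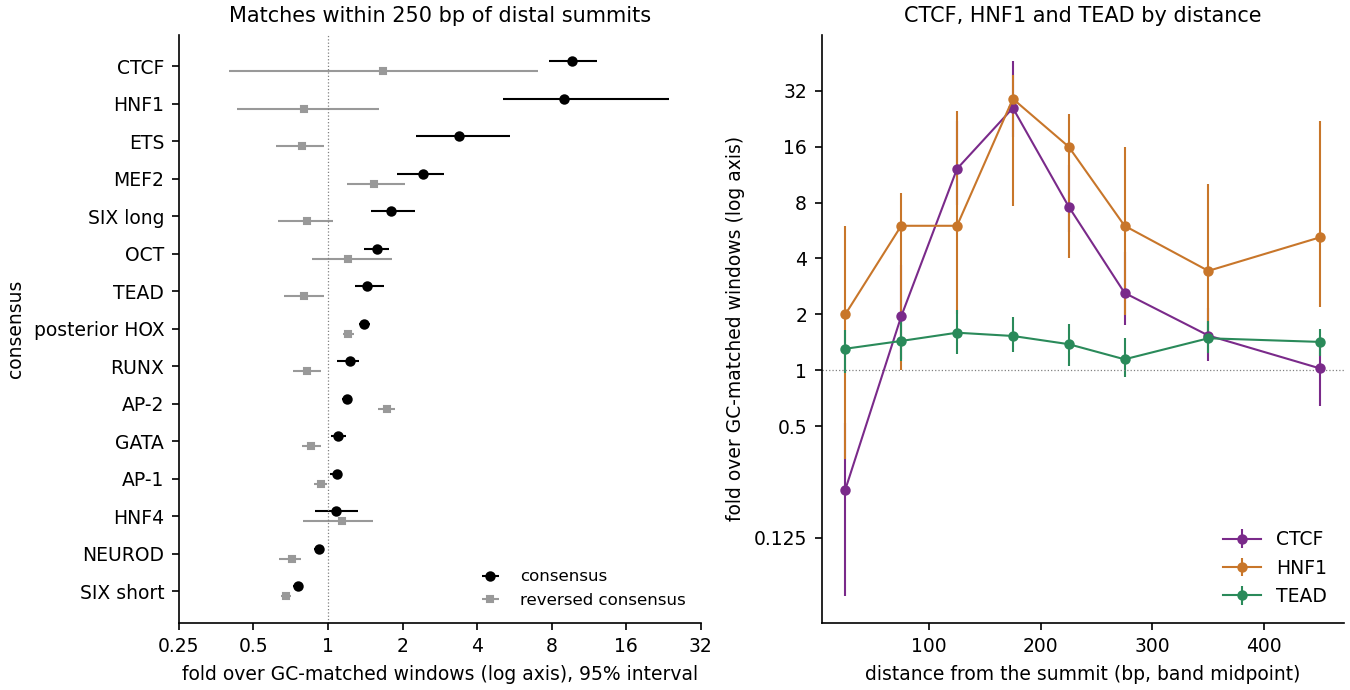
Left, fold of the share of distal peaks with a consensus match within 250 bp of the summit over GC-matched random windows (log axis), for each consensus and its reversed form, with 95% bootstrap intervals; CTCF and HNF1 stand highest, at 9.63 and 9.0. Right, the same fold (log axis) for CTCF, HNF1 and TEAD by distance of the match from the summit in bp, where CTCF, at 25.9, and HNF1, at 29, are highest between 150 and 200 bp.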

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

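The tests of explanations in this part were all chosen after the results were seen. No biological explanation was tested against another group of samples, since the design has a single group.

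On unplaced or unlocalized scaffolds, sequence of the assembly with no known position along a chromosome that no comparison used, there were 11 replicated peaks on 6 scaffolds, listed here only because they are a signal in data left out; each of the 4 lists held 11 to 13, and whether that number is unusual was not tested. Their median fold was 14.1 and the highest 22.1.

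The marking of 9 of the 11 genes of the brain list in kidney stood out, since these genes serve another organ. Promoters with many CpG dinucleotides may carry H3K4me2 whatever the tissue, and random lists matched on CpG content had a mean of 9.09 marked genes, with 95% of them between 7 and 11. Nerve or neural crest cells in the dissected tissue are another candidate source, and for these the 6 of 9 marked genes of the neural crest and peripheral neuron list lay beside a CpG-matched mean of 6.72, with 95% between 5 and 8, while Phox2b, Plp1 and Th had no replicated peak at the TSS. This leaves the contribution of such cells open, because a small share of cells could add weak peaks that this count does not separate from CpG content. A count at the CpG-matched mean does not require such cells, but the CpG-matched range of the brain list reached all 11 genes. No count could have lain above that range, so the comparison could not have come out against CpG content.

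The broad marking of nephron progenitor, ureteric bud and stroma genes was set against both base composition and gene class. CpG content of the promoters would predict like breadth in matched random lists, but the upper end of the range that held 95% of their medians was 3051 bp, below the observed median of 6224.5 bp over the 44 genes. If breadth belonged to developmental transcription factor genes in any tissue, those of other tissues' lists would be broad. The 20 there had a median of 1780 bp (95% bootstrap interval 978 to 2296 bp). That median lay within the 543 to 2993 bp that held 95% of the medians of random lists. Its interval was below that of 5012 to 8545 bp for the 44 genes. The 44 include genes of other classes, such as Aqp2 and Pdgfra, so the gap between the intervals is not a comparison within a single class. The 20 came only from lists that the breadth test had not called, and the 44 from lists that it had called. Both sides were thus chosen with their breadth known, so the gap cannot decide whether breadth belongs to this gene class. Another hypothesis is that breadth goes with use of these genes in the kidney, which was not tested, as no expression data were analysed here.

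The CTCF consensus was enriched within 250 bp of distal summits but not over the part within 100 bp taken as a whole, where only 44 of the 870 peaks with a match had it (5.06%, compared with 42.0% of matched random windows). By distance, the CTCF fold was 0.227 (0.0606 to 0.522) within 50 bp, 1.95 (1.15 to 3.69) between 50 and 100 bp, 25.9 (17.9 to 46.1) between 150 and 200 bp and 1.02 between 400 and 500 bp, and HNF1 was also highest between 150 and 200 bp (29.0, 7.66 to 39.0; 29 peaks and 1 window). GC and CpG content at the summit do not account for the lack of enrichment within 100 bp as a whole. Against windows matched on both there, the fold was 1.06 (0.625 to 1.67), far under the 9.63 within 250 bp. The low fold within 50 bp was not set against windows matched in this way. Summits placed to one side of bound sites are a candidate explanation that stays open: of the matches above the number in windows, 0.260% lay within 100 bp for CTCF, and over the 11 other consensus sequences with intervals above 1 the median was 20.0% (14.4 to 34.1), with single values from −31.7% for AP-1 to 54.4% for AP-2, which does not decide against a bound of 20%. A marked nucleosome beside the CTCF site stays open too, because enrichment within 250 bp but not over the first 100 bp already placed the highest fold beyond 100 bp, and that value could not have come out against it.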

How the results depend on the processing

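All alternatives here were planned except the omission of Hox genes, which was chosen after the results were seen. It left the same 8 breadth calls and 5 domain calls. The higher coverage of Hox groups 1 to 11 passed its exact test under each alternative, by 550 to 2834 bp, and 12 consensus intervals lay above 1 with either replicate's peaks. Of 583 values for single lists, features and consensus sequences under the alternatives, 514 kept direction and side of the threshold or, without a test, stayed within the replicate spread, 24 newly passed, 18 no longer passed, 10 without a test moved beyond that spread and 17 changed direction. Depth is unknown, so its effect on weak peaks could not be examined, and the cause of the changes below was not tested, except that fewer weak peaks entered under stricter settings. With an overlap of 50% of either peak, 76.9% and 76.4% of replicate 1 and 2 peaks were shared, with a rho of 0.856, and 65.0% of pooled peaks met that overlap in both. With −log10 p of at least 5, these were 84.6%, 85.9% and 0.854, the pooled share kept was 86.8%, the promoter share 37.0%, and 2 lists passed for distal peaks. Among the strongest 25000 peaks, 95.1% of each replicate's were shared, with a rho of 0.864. With either replicate's own peaks, the promoter share was 31.5% to 31.9%, the summit density ratio 0.533 to 0.565, 6 lists passed for distal peaks, and 50% to 75% of proximal tubule genes were marked. With a promoter window of 2.5 kb the promoter share was 43.4%, 2 lists passed for marking and 77.8% of neural crest genes were marked; with 500 bp 10 lists passed, and with any overlap the promoter share was 39.2%. Against CpG-matched random lists, uncalled medians changed side at 1060.5 bp for proximal tubule, 176.5 bp for erythroid, 500 bp for adrenal cortex and 688 bp for muscle and heart. With means of distal peaks, 5 lists passed, and uncalled means changed side at 4.20 for loop and distal tubule, 0.889 for neural crest and 0.667 for muscle and heart. With gaps of 3 kb merged, 3 lists passed for domains. Uncalled domain shares changed side at 11.1% for brain and 0% for housekeeping with no gap merged, 12.5% for proximal tubule with 3 kb, and 12.5% for proximal tubule and 11.1% for brain in the 1000 longest domains. Within 100 bp of the summit, the fold was 0.872 for CTCF and 1.01 for NEUROD, and for HNF1 none could be given, and AP-2 was at 0.988 against windows matched on GC and CpG content. No paired analysis was possible because the series has a single group.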

Other observations

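The test in this part, a count of distal peaks beside HoxD, was chosen after the results were seen, and so were the genes named.

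The gene-poor regions on both sides of the HoxD cluster differed in the number of distal H3K4me2 peaks. In the 1 Mb beyond Hoxd1 (chromosome 2, 74765143 to 75765142, mm10) there were 49 distal replicated peaks (56 ± 1.41 in the replicates, SD, n = 2), of which 29 lay nearest to Mtx2. In the 1 Mb before Hoxd13 (73668310 to 74668309) there were 19 (19.5 ± 2.12), of which 9 lay nearest to Atp5g3. The difference between the sides exceeded the spread between replicates. Among 10000 random windows of 1 Mb, which had a median of 7 distal peaks and a 95th percentile of 29, 0.480% had at least as many as the side of Hoxd1 and 17.7% as many as the side of Hoxd13. The share of windows describes these peaks and is not a p-value for the difference between the sides.

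In the lists for mature nephron segments, the transcription factor genes had more covered base pairs near the TSS than most genes for transport proteins. In the loop and distal tubule list, the transcription factor genes Pou3f3, Irx2, Sim2 and Irx1 had 8738, 6779, 3803 and 3700 bp covered within 5 kb of the TSS, whereas Umod, Slc12a1, Slc12a3, Kcnj1 and Cldn16, which encode uromodulin, cotransporters, a channel and a claudin, had 0 bp each. Calb1, which encodes a calcium-binding protein, had 1481 bp. Umod had 347 bp in replicate 1 and 0 bp in replicate 2. In the proximal tubule list, the transcription factor genes Hnf1a and Hnf4a had 4791 bp and 3606 bp. The transporter genes Slc5a2 and Slc5a12 had 0 bp, Slc3a1 235 bp, Slc22a6 931 bp and Slc34a1 2187 bp. Replicates 1 and 2 gave 2224 and 2805 bp at Hnf4a, 2337 and 842 bp at Slc34a1, and 730 and 226 bp at Slc22a6. In replicate 1, Slc34a1 thus exceeded Hnf4a. The endocytic receptor genes differed, with 5341 bp at Lrp2 and 375 bp at Cubn, which had 665 bp in replicate 1 and 0 bp in replicate 2. CpG content near the TSS (observed over expected) differed too. In the loop and distal tubule list it was 0.655 to 0.917 at the transcription factor genes and 0.0448 to 0.330 at the genes with 0 bp. In the proximal tubule list it was 0.352 at Hnf1a and 0.306 at Hnf4a, above most transporter genes but below Slc3a1 at 0.457. No test was made of these groups within the lists.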
